A study of Mus musculus with 6 samples.

How the data were processed

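Gene expression was measured on Affymetrix Mouse430_2 arrays in T cells recovered from lymphopenic mice, BALB/c animals lacking Rag1 and so lacking T and B cells of their own. Per the labels, the hosts had received natural regulatory T cells (nTreg) together with 500000 regulatory T cells induced in culture (iTreg), both of wild-type origin. After 125 days, CD4-stained cells from the spleens and mesenteric lymph nodes of 14 treated mice were sorted by flow cytometry and pooled. The EGFP reporter marks expression of Foxp3, the transcription factor that defines regulatory T cells, and Thy1.1 is an allelic surface mark of the transferred iTreg cells. nTreg cells were EGFP-positive and Thy1.1-negative, iTreg cells were positive for both, and ex-iTreg cells were Thy1.1-positive cells that had no EGFP. Sort purity averaged 98.96 ± 0.14% and viability 84.31% over the laboratory's sorts, per the labels, and neither is given for these pools.

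The 6 arrays form 3 groups of 2, each array being 1 replicate pool. The labels do not say whether the 2 pools of a group held cells of separate mice, so every p-value measures only the spread between these pools, which may be technical. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes; the software and its version are not given in the sources used here. Array medians lay between 5.47 and 5.49. The authors' comparison with naive conventional T cells is not analysed here.

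Of 45101 probe sets, 64 were array controls. Gene names came from the platform annotation, which gave 1 symbol for 34945 of the 45037 remaining probe sets, several for 932 and none for 9160; 34754 were matched by Entrez identifier to a RefSeq gene table and 0 symbols needed updating. That table was used only for names, chromosomes and gene order, and no coordinates are printed because the files name no genome build. Tested probe sets were non-control probe sets above the median of all values (5.48) in at least 2 of the 6 arrays, which kept 23484. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 11015 genes.

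Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model with a mean per group, so that all arrays shared 1 estimate of the spread with 3 residual and 3.37 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 23484 probe sets, with a threshold of 0.05. A 2-fold difference of group means was counted beside the test, because the authors' design used a 2-fold criterion against conventional T cells. An exact test of 2 arrays against 2 cannot give a two-sided p below 0.33, so all calls rest on limma's pooled spread.

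Genes named in the text followed a rule set before the data were examined. It took the 12 largest differences in each direction among called genes whose 2 pools of one group both lay above both pools of the other, passing over Riken and Gm models. An earlier version of the script also passed over other clone names, which the rule does not; following the rule put BC018473 in the place of Sgip1 in iTreg minus nTreg. It added up to 4 members of each gene list by t statistic, and always, among genes fixed by name, Foxp3, Il2ra, Ctla4, Ikzf2, Nrp1, Itgae, Il10, Ifng, Il17a, Tbx21, Gata3, Bcl6, Il7r and Ccr7. Further list members are named to say which moved, as are genes in the tests of technical explanations.

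The 29 gene lists, also set before the data were examined, were the Treg cell signature, thymic Treg cell markers, suppressive mediators, Th1, Th17 and Th2 cell genes, follicular helper genes, naive and resting state, effector memory state, inhibitory receptors, chemokine receptors and homing, T cell identity, IL-2 and STAT5 targets, TGF-beta response, AP-1 and immediate early genes, heat shock and stress, interferon response, NF-kappaB targets, proliferation, glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, and markers of B cells, myeloid cells, dendritic cells, CD8 T and NK cells, erythroid cells and stromal and endothelial cells. They were written from general knowledge and overlap; 25 of the 32 signature genes stand in another list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists within a comparison. The alternatives were camera with an estimated correlation, which has only the 3 residual degrees of freedom, and the rotation test fry.

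The model was tested on simulated data with the spread of the real arrays, noise drawn independently for each probe set, and 200 changed probe sets among 23484. In the simulated comparison of iTreg with nTreg it recovered 41.8% of 1.5-fold, 85.1% of 2-fold and 98.5% of 4-fold changes. For ex-iTreg against iTreg these shares were 56.7%, 89.6% and 100%, and for ex-iTreg against nTreg 46.3%, 79.1% and 100%. False calls were 10 of 160, 11 of 175 and 10 of 160 calls in these 3 comparisons. In the real data 29.1%, 37% and 36.4% of probe sets were called. The Benjamini-Hochberg cutoff depends on the share changed, so the recovered shares do not carry over to the real comparisons. In simulated lists among 11015 genes, camera called 0 of 29 unchanged lists in each of the 3 comparisons. It called the 1 list of 20 genes shifted by 0.5 log2 units in each of them. With an estimated correlation the shifted list was missed in iTreg against nTreg. The independent noise gave these simulated lists no inter-gene correlation. The real lists had estimated correlations between -0.133 (dendritic cell markers) and 0.226 (interferon response). The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes. The alternatives changed the probe set filter, the normalization, the variance prior, the array weights, the probe sets per gene, the arrays in the fit and the list test, and left out each array in turn. Other calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.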

Results

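The data were 6 expression arrays, 2 for each of 3 CD4 T cell populations recovered from the same hosts. The populations were natural regulatory T cells (nTreg), culture-induced regulatory T cells that still expressed the Foxp3 reporter (iTreg), and cells of induced origin without the reporter (ex-iTreg). Values are log2 expression as deposited. Unless stated otherwise, a difference is given in log2 units ± its standard error from limma, with n = 2 arrays per group. The 2 arrays of a group correlated across probe sets with r between 0.9957 and 0.9972, and arrays of different groups with r between 0.9563 and 0.9787; probe sets are not independent replicates. The first principal component held 64.6% of the variance and ordered the populations nTreg, iTreg, ex-iTreg. The second component held 26.8% and set iTreg arrays (-29.56 and -31.20) apart from nTreg (20.65 and 20.04) and ex-iTreg arrays (9.30 and 10.77). A group mean under the filter level of 5.48 is near background, so the size and rank of a difference from it are not resolved. Beyond the largest differences, listed under each comparison, this limits Ccr8 and Ms4a1 in iTreg and ex-iTreg arrays, Klrc1 and Il21 in nTreg and iTreg arrays, Cd79b and Cd8b1 in ex-iTreg arrays and Il17a and Uty in nTreg arrays.

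The label of each population rests on Foxp3, and the array could not check it. Its 1 annotated probe set read between 3.99 and 4.29 in all 6 arrays, below the filter at 5.48, and was not tested. Thy1 differed by 0.73 ± 0.07 in iTreg minus nTreg and by 0.38 ± 0.07 in ex-iTreg minus nTreg (adjusted p = 0.0013 and 0.00925, limma); whether its probe set separates the Thy1.1 and Thy1.2 alleles was not tested.

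**Figure D1:**
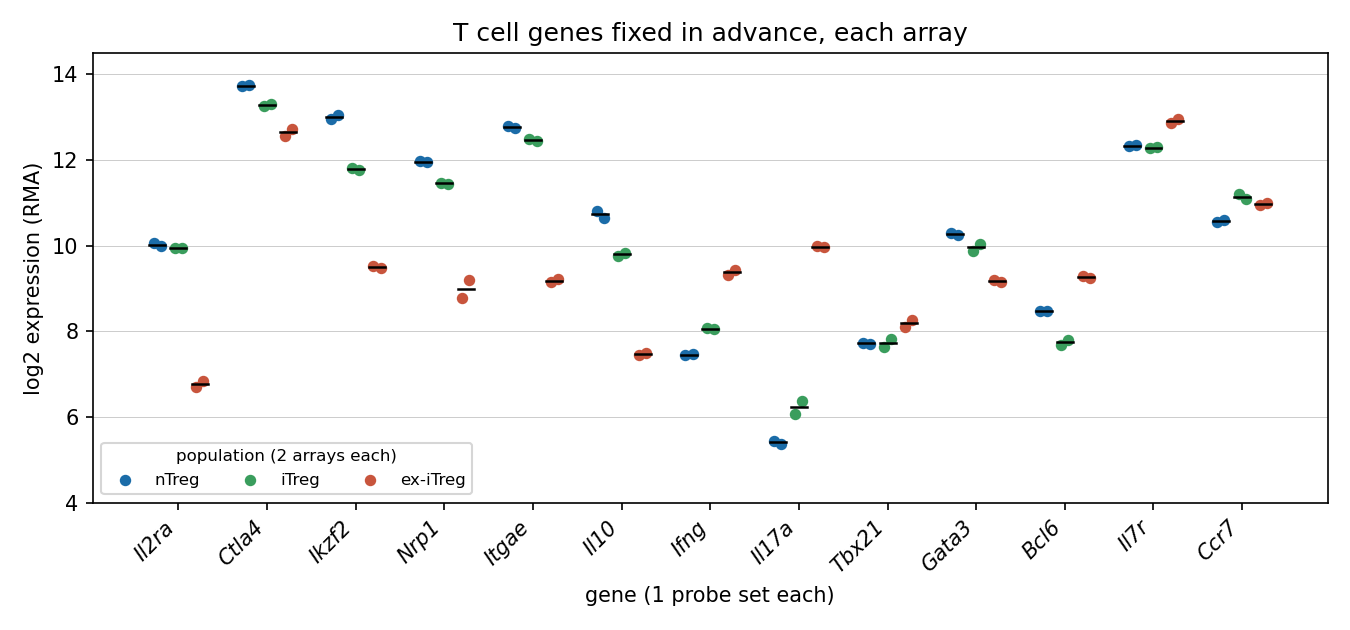
Log2 expression (vertical axis, RMA) of 13 T cell genes fixed in advance (horizontal axis), with 1 point per array, 2 arrays per population, and a bar at each population's mean. Il2ra read 10.0 in nTreg, 9.95 in iTreg and 6.77 in ex-iTreg arrays, while Il17a read 5.42, 6.23 and 9.98.

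The first comparison asks how induced regulatory cells that kept the reporter differed from natural ones after sharing a host. iTreg arrays were lower for many Treg cell genes, among them Ikzf2, which encodes the transcription factor Helios, and Il10, an anti-inflammatory cytokine. They were higher for genes of naive or resting T cells, such as Dapl1, Igfbp4 and Actn1. Il2ra, the high-affinity IL-2 receptor chain, differed by only -0.08 ± 0.08, and the test found no difference (adjusted p = 0.483, limma). Of 23484 probe sets, 603 differed at least 2-fold, 200 higher and 403 lower in iTreg arrays, and all of these passed limma's test.

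Among the named increases in iTreg arrays were Dapl1, at 3.35 ± 0.19, and Myo6, an unconventional myosin, at 3.31 ± 0.09. Igk, an immunoglobulin light chain, followed at 3.10 ± 0.08 on the probe set used, while its other probe set moved by -0.70, so its direction depends on the probe set. Sh3bgrl2, Pde3b, Plac8, Igfbp4 and Tdrp rose by 2.79, 2.39, 2.25, 2.17 and 2.06. C1qb, a complement component made by macrophages, rose by 2.01 ± 0.18, and Kdm5d, a gene of the Y chromosome, by 1.92 ± 0.20. Tgm2, a transglutaminase, and Dse completed the group at 1.90 and 1.87. Among the decreases was Gdpd3, a lysophospholipase D, which fell from 12.6 to 8.18, a 21.5-fold difference. BC018473, a gene with only a clone name, fell by 3.46 ± 0.15, Zc3h12c fell by 3.19 ± 0.15, and Mid1, a ubiquitin ligase, fell by 2.81 ± 0.06. Plagl1, Prickle1, Swap70 and Epcam fell (-2.33, -2.30, -2.15 and -2.12), but another probe set of Epcam moved by -0.14 (adjusted p = 0.406, limma). Cd83, Hey1, Gpr160 and Matn2 fell (-2.12, -2.08, -2.08 and -2.06). The lower mean of 7 of these 24 genes lay under the filter level: Dapl1 (4.90), Igk (4.65) and Dse (3.86) in nTreg arrays, and BC018473 (4.37), Zc3h12c (4.23), Prickle1 (5.46) and Matn2 (4.78) in iTreg arrays. Adjusted p-values of these 24 genes were at most 0.00148 (limma).

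Of 27 tested members of the Treg cell signature, 19 fell in iTreg relative to nTreg arrays, 2 rose and 6 did not pass the test; adjusted over the list alone, 19 fell and 3 rose. The list's median was -0.51 (camera adjusted p = 1.47e-08, limma), but adjusted p = 0.175 with an estimated correlation. Ikzf2 fell by 1.22 ± 0.07 and Ikzf4, its relative, fell by 1.06 ± 0.07. Ccr8, a chemokine receptor, fell from 6.57 to 5.14, under the filter level, and Klrg1, a lectin-like inhibitory receptor, fell by 1.28 ± 0.06. Ctla4, an inhibitory receptor, fell by 0.45 ± 0.07. Gpr83 and Socs2 were the members that rose, Socs2 on 3 of its 4 other probe sets as well (0.43, 0.62 and 0.28) but not on the remaining one (0.22, adjusted p = 0.152, limma). Among 6 thymic Treg cell markers, 5 fell and Gpr83 rose, with a median of -1.14 (camera adjusted p = 0.000265, limma; adjusted p = 0.175 with an estimated correlation). Nrp1, a semaphorin receptor in that list, differed by -0.51 ± 0.13 (adjusted p = 0.0298, limma), a call lost without any one of the nTreg or iTreg arrays. Its other probe sets differed by -0.33, -0.43 and -0.41 (adjusted p = 0.0186, 0.00512 and 0.0116, limma). The call of Itgae, an integrin of tissue-resident T cells, at -0.30 ± 0.07, was lost without nTreg pool 1, iTreg pool 1 or iTreg pool 2. Its other probe set differed by -0.44 (adjusted p = 0.00376, limma). The other probe sets of Nrp1 and Itgae were not examined with an array left out. Of 14 suppressive mediators, 8 fell and 1 rose (camera adjusted p = 0.00495, limma; adjusted p = 0.244 with an estimated correlation). Il10 fell by 0.94 ± 0.08 and Itgb8, an integrin chain that activates TGF-beta, fell by 1.40 ± 0.11, while Prf1, the pore-forming protein perforin, rose by 0.82 ± 0.07.

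Naive and resting state genes rose in 13 of 16 cases and fell in 0, with a median of 0.57 (camera adjusted p = 5.05e-06, limma; adjusted p = 0.175 with an estimated correlation). Actn1, encoding alpha-actinin, rose by 1.32 ± 0.06, Il6ra, an IL-6 receptor chain, by 1.46 ± 0.10 and Ccr7, a lymph node homing receptor, by 0.57 ± 0.07. Another probe set of Il6ra differed by 0.19 (adjusted p = 0.135, limma). Effector memory genes fell in 13 of 23 cases and rose in 2 (camera adjusted p = 1.44e-05, limma; adjusted p = 0.175 with an estimated correlation); Prdm1, encoding the repressor Blimp-1, fell by 0.79 ± 0.07. Follicular helper genes fell in 7 of 11 cases and rose in 1 (camera adjusted p = 0.000759, limma; adjusted p = 0.175 with an estimated correlation). That 1 was Il21, whose means of 3.59 and 4.07 both lay under the filter level, so its call compares readings near background. Pdcd1, encoding the receptor PD-1, fell by 1.82 ± 0.06, Tox fell by 1.67 ± 0.16 and Bcl6, a follicular helper regulator, fell by 0.73 ± 0.07 on the probe set used. The other Bcl6 probe set differed by 0.03 (adjusted p = 0.836, limma), so that fall depends on the probe set. Inhibitory receptors fell in 5 of 10 cases (camera adjusted p = 0.00749, limma, and 0.244 with an estimated correlation). Of these, Pdcd1, Tox and Cd200 also stand in the follicular helper list and Ctla4 in the Treg cell signature.

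Th1 cell genes were mixed, 4 rising and 4 falling among 15 (camera adjusted p = 0.986, limma). Ifng, the cytokine interferon gamma, rose by 0.61 ± 0.07, and Tbx21, its regulator, differed by 0.00 ± 0.09. Of 12 Th17 cell genes, 7 rose and 3 fell, and the list did not pass (camera adjusted p = 0.254, limma). Il17a rose by 0.81 ± 0.11 from 5.42, under the filter level, and Rora fell by 1.19 ± 0.06. Of 7 Th2 cell genes, 3 fell and 0 rose (camera adjusted p = 0.0197, limma; adjusted p = 0.244 with an estimated correlation). Gata3, the Th2 regulator, was among them at -0.32 ± 0.08, and its call was lost without any array except iTreg pool 2 (adjusted p from 0.0542 to 0.115, limma).

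Markers of other cell types also differed. Of 19 myeloid cell markers, 14 rose in iTreg relative to nTreg arrays and 0 fell, with a median of 0.43 (camera adjusted p = 1.39e-06, limma; adjusted p = 0.175 with an estimated correlation). C1qa rose by 1.64 ± 0.12, Adgre1, a macrophage surface receptor, by 1.47 ± 0.09 and Csf1r, the macrophage growth factor receptor, by 1.22 ± 0.06. Erythroid markers rose in 5 of 6 cases (camera adjusted p = 0.00619, limma; adjusted p = 0.268 with an estimated correlation). The B cell list did not pass (camera adjusted p = 0.636, limma), with a median of 0.23 over 9 tested members. Of these 4 rose, Jchain, Cd74, H2-Aa and H2-Ab1 (0.47, 0.81, 0.64 and 0.40), and 2 fell, Cd79b and Ms4a1 (-1.19 and -1.10). The poly-A controls, added to the RNA before labelling, were higher by 1.43. The X-linked transcript Xist fell by 1.29 and the Y-linked genes Eif2s3y and Uty rose by 1.15 and 1.38. Adjusted over the list alone, 2 rose and 8 fell among suppressive mediators, 13 rose and 1 fell among naive and resting state genes, 2 rose and 15 fell among effector memory genes, 1 rose and 8 fell among follicular helper genes, 5 rose and 4 fell among Th1 cell genes, 0 rose and 4 fell among Th2 cell genes and 17 rose and 0 fell among myeloid markers; the counts of the other lists described for this comparison did not change. In all, 6826 probe sets passed limma's test, 3420 higher and 3406 lower. The balance turned on single arrays, with 2975 higher and 2185 lower without nTreg pool 1 and 2034 higher and 2921 lower without nTreg pool 2. The count was 3420 without iTreg pool 2 and 4002 without iTreg pool 1, and 0 of the 16 lists called by camera were called with an estimated correlation.

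The second comparison sets cells of induced origin that had lost the reporter against those that kept it. ex-iTreg arrays were lower for most Treg cell genes and higher for the cytokines Il21, Il17a and Il2. Il17a was 13.4-fold higher. Il21, a cytokine of follicular helper and Th17 cells, and Il2, the T cell growth factor, rose from iTreg means under the filter level (4.07 and 4.32), so no fold is given for them. Il2ra, the receptor chain for that factor, was 9.04-fold lower and Itgae 9.74-fold lower. In total 859 probe sets differed at least 2-fold, 403 higher and 456 lower in ex-iTreg arrays, all past limma's threshold.

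Among the increases were Il21, at 4.78 ± 0.10, and Smoc2, a secreted calcium-binding protein, at 4.24 ± 0.11. Il17a rose by 3.75 ± 0.11 and Gzmk, a granule protease, by 3.71 ± 0.09. Slc22a4, Il2, Pdlim4 and Atp8b4 rose by 3.68, 3.43, 3.34 and 3.15. The lectin-like receptors Klrk1 (NKG2D) and Klrd1 (CD94) rose by 3.14 ± 0.10 and 3.01 ± 0.07. Il1rl2, the IL-36 receptor, and Tbc1d4, a regulator of glucose transporter traffic, rose by 2.81 and 2.68. Among the decreases were Itgb8, which fell by 4.26 ± 0.11, and Cyp4f18, which fell by 3.80 ± 0.08. Tktl1, Gpr83, Nxpe4 and Klrg1 fell (-3.66, -3.54, -3.48 and -3.42). Itgae, Itih5 and Il2ra fell (-3.28, -3.25 and -3.18). Csf1, a macrophage growth factor, Penk, the enkephalin precursor, and Sdc4, a proteoglycan, fell (-3.16, -3.05 and -3.03). The lower mean of 11 of these 24 genes lay under the filter level: Il21, Smoc2, Slc22a4, Il2, Klrk1 and Il1rl2 in iTreg arrays, and Itgb8, Cyp4f18, Tktl1, Nxpe4 and Itih5 in ex-iTreg arrays. Adjusted p-values of these 24 genes were at most 2.28e-05 (limma).

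Of 27 Treg cell signature genes, 23 fell and 2 rose, with a median of -1.69 (camera adjusted p = 1.32e-11, limma), but adjusted p = 0.125 with an estimated correlation. The 2 that rose were Plagl1, by 1.33 ± 0.06, and Nebl. Ikzf2 fell by 2.29 ± 0.07, Nrp1 fell by 2.46 ± 0.13 and Ctla4 fell by 0.64 ± 0.07. Ctla4 still read 12.6 in ex-iTreg arrays. The thymic markers fell in 5 of 6 cases, Plagl1 being the other (camera adjusted p = 0.0011, limma; adjusted p = 0.125 with an estimated correlation). Suppressive mediators fell in 12 of 14 cases and rose in 0 (camera adjusted p = 1.39e-06, limma; adjusted p = 0.125 with an estimated correlation). Il10 fell by 2.33 ± 0.08, Ebi3, a subunit of IL-35, fell by 2.34 ± 0.10 and Gzmb, the protease granzyme B, also fell (-1.50 ± 0.07). IL-2 and STAT5 targets fell in 9 of 13 cases, and Il2 itself was the 1 member that rose (camera adjusted p = 0.000312, limma; adjusted p = 0.125 with an estimated correlation). Socs2 and Cish, feedback regulators of cytokine signalling, fell (-1.70 and -1.35).

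Th1 cell genes rose in 10 of 15 cases and fell in 2, Cxcr3 and Il12rb1, with a median of 0.58 (camera adjusted p = 4.63e-05, limma; adjusted p = 0.125 with an estimated correlation). Ccl5, a chemokine, rose by 2.52 ± 0.06, Fasl, a death ligand, by 2.22 ± 0.10 and Ifng by 1.31 ± 0.07. Tbx21 differed by 0.47 ± 0.09, and its call was lost without iTreg pool 1 (adjusted p = 0.0535, limma) or ex-iTreg pool 2 (0.0672). Th17 cell genes rose in 7 of 12 cases and fell in 0 (camera adjusted p = 0.000811, limma; adjusted p = 0.172 with an estimated correlation), Il17re among them at 1.87 ± 0.08. Follicular helper genes rose in 7 of 11 cases and fell in 1, Cd200 (camera adjusted p = 0.00209, limma; adjusted p = 0.125 with an estimated correlation). Bcl6 rose by 1.53 ± 0.07 and Tox2 by 1.84 ± 0.09. Th2 cell genes fell in 6 of 7 cases (camera adjusted p = 0.000811, limma; adjusted p = 0.125 with an estimated correlation), Gata3 at -0.79 ± 0.08 and Nfil3 at -1.27 ± 0.06.

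NF-kappaB targets fell in 9 of 11 cases (camera adjusted p = 0.000811, limma; adjusted p = 0.125 with an estimated correlation), Icam1, an adhesion molecule, at -1.58 ± 0.08. Interferon response genes fell in 13 of 21 cases and rose in 1, Mx1 (camera adjusted p = 0.00266, limma; adjusted p = 0.388 with an estimated correlation), with Gbp3 at -1.65 ± 0.06 and Irf1 at -1.03 ± 0.06. Il7r, the IL-7 receptor chain, rose by 0.63 ± 0.07, and Ccr7 differed by -0.17 ± 0.07 (adjusted p = 0.09, limma). CD8 T and NK cell markers rose in 6 of 8 cases, with a median of 1.81 (camera adjusted p = 0.000959, limma; adjusted p = 0.125 with an estimated correlation). Klrc1 rose by 1.80 ± 0.08 from 3.92, under the filter level, while Cd8b1, the CD8 beta chain, fell by 0.75 and Prf1 fell as well. Cd8a, the CD8 alpha chain, was among the members that rose.

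Myeloid markers fell in 15 of 19 cases (median -0.65, camera adjusted p = 2.32e-06, limma), B cell markers in 8 of 9 (median -0.65, camera adjusted p = 0.000312) and erythroid markers in 5 of 6 (median -0.59, camera adjusted p = 0.00724). With an estimated correlation the adjusted p of these 3 lists was 0.125, 0.125 and 0.248. Ighm, an immunoglobulin heavy chain in the B cell list, fell by 1.06 ± 0.06 on the probe set used; of its other probe sets 1 also fell (-1.77), 1 rose by 0.21, and the rest differed by 0.29 and 0.11 (adjusted p = 0.127 and 0.565, limma). The poly-A controls differed by -2.79. Xist fell by 2.60, and Eif2s3y and Uty rose by 0.75 and 0.53, while Kdm5d differed by 0.10 ± 0.20 (adjusted p = 0.74, limma). Adjusted over the list alone, 1 rose and 10 fell among IL-2 and STAT5 targets, 7 rose and 2 fell among follicular helper genes, 0 rose and 7 fell among Th2 cell genes, 0 rose and 10 fell among NF-kappaB targets, 2 rose and 13 fell among interferon response genes and 0 rose and 17 fell among myeloid markers; the counts of the other lists described for this comparison did not change. In all 8694 probe sets passed limma's test, 4160 higher and 4534 lower. That count was 5719 without iTreg pool 2, 5270 without ex-iTreg pool 1 and 4971 without ex-iTreg pool 2, and 0 of the 14 lists called by camera were called with an estimated correlation.

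**Figure D2:**
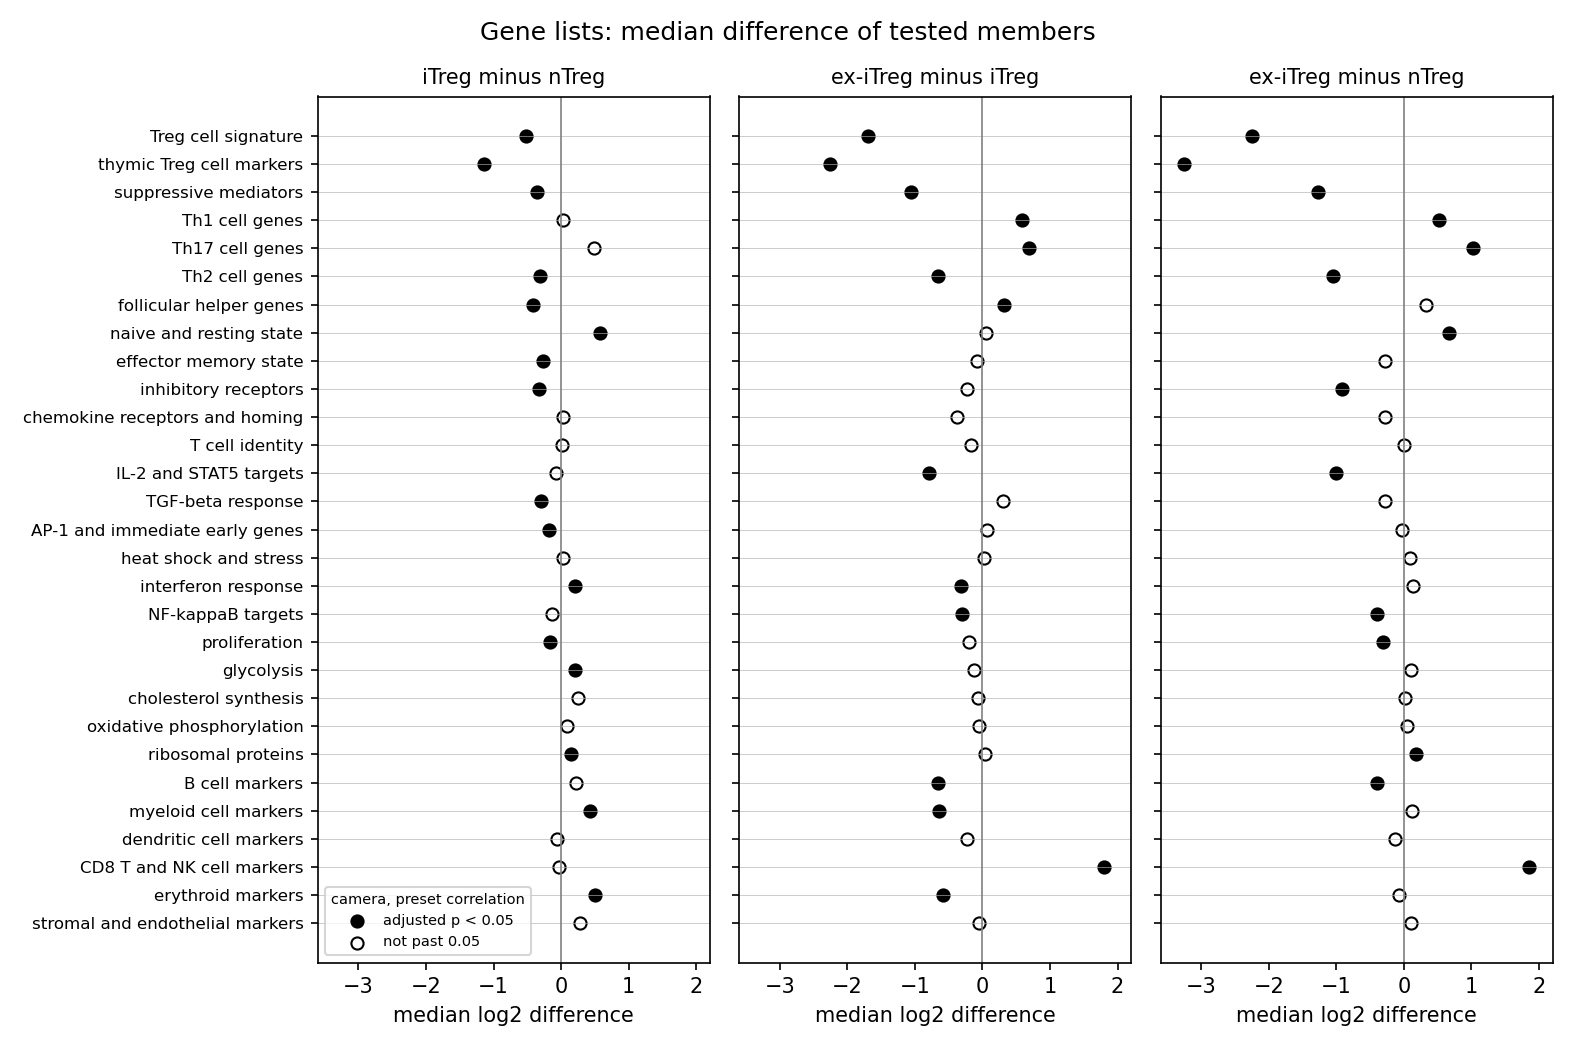
Median log2 difference of the tested members (horizontal axis) of each of 29 gene lists (vertical axis) in 3 comparisons, filled where camera with the preset correlation passed adjusted p 0.05. The Treg cell signature had medians of -0.51, -1.69 and -2.25 from left to right; no list was called with an estimated correlation.

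The third comparison sets ex-iTreg cells against natural regulatory T cells and held the most 2-fold differences, 1283 probe sets, 461 higher and 822 lower. Gdpd3 was 63.9-fold lower in ex-iTreg arrays and Pde3b, a cyclic nucleotide phosphodiesterase, 29.6-fold higher. Itgb8 fell to 3.70 and Il21 and Il17a rose from 3.59 and 5.42, all under the filter level, so no fold is given for them. All 1283 probe sets passed limma's test.

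Smoc2, Pdlim4, Dapl1, Tdrp and Atp8b4 were higher in ex-iTreg than nTreg arrays by 4.49, 4.16, 4.14, 4.13 and 4.07. Tgfbr3, the TGF-beta co-receptor betaglycan, rose by 4.03 ± 0.08, Klrd1 by 3.91 ± 0.07, and Slc22a4 and Hs3st3b1 by 3.74 and 3.68, but other probe sets of Hs3st3b1 differed by 0.79 and by 0.06 (adjusted p = 0.0148 and 0.804, limma). Klrg1 fell by 4.70 ± 0.06, Tktl1 fell by 4.68 ± 0.11 and Epcam fell by 4.27 ± 0.07, though another Epcam probe set moved by -0.25 (adjusted p = 0.149, limma). Itih5, Matn2, Ccn4 and Cd81, a tetraspanin, fell (-4.04, -4.00, -3.92 and -3.91). Xist, Nxpe4 and Penk fell (-3.88, -3.88 and -3.85). The lower mean of 16 of these 24 genes lay under the filter level: Il21, Il17a, Smoc2, Pdlim4, Dapl1, Atp8b4, Klrd1, Slc22a4 and Hs3st3b1 in nTreg arrays, and Itgb8, Tktl1, Epcam, Itih5, Matn2, Ccn4 and Nxpe4 in ex-iTreg arrays. Adjusted p-values of these 24 genes were at most 5.39e-05 (limma).

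Of 27 Treg cell signature genes, 25 fell and 1, Nebl, rose, with a median of -2.25 (camera adjusted p = 2.65e-19, limma; adjusted p = 0.106 with an estimated correlation). Swap70 fell by 3.84 ± 0.08, Itgae fell by 3.58 ± 0.07 and Ikzf2 fell by 3.51 ± 0.07. Nrp1 and Il2ra fell (-2.97 and -3.25), and Ctla4 fell by 1.09. All 6 thymic markers fell (median -3.25, camera adjusted p = 2.54e-07, limma; adjusted p = 0.127 with an estimated correlation). Suppressive mediators fell in 12 of 14 cases and Prf1 rose (camera adjusted p = 1.61e-07, limma; adjusted p = 0.127 with an estimated correlation), with Il10 at -3.26 ± 0.08. IL-2 and STAT5 targets fell in 10 of 13 cases, Il2 and Bcl2 rising (camera adjusted p = 0.000326, limma; adjusted p = 0.127 with an estimated correlation).

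Th1 cell genes rose in 10 of 15 cases and fell in 2 (camera adjusted p = 0.000371, limma; adjusted p = 0.21 with an estimated correlation), Ifng by 1.92 ± 0.07, Fasl by 2.56 ± 0.10 and Ccl5 by 1.97 ± 0.06. Tbx21 differed by 0.47 ± 0.09, a call lost without ex-iTreg pool 2 (adjusted p = 0.0648, limma). Th17 cell genes rose in 7 of 12 cases and fell in 4, Rora, Ahr, Batf and Maf (camera adjusted p = 0.0382, limma; adjusted p = 0.322 with an estimated correlation). Th2 cell genes fell in 6 of 7 cases (camera adjusted p = 0.000185, limma; adjusted p = 0.127 with an estimated correlation), Gata3 at -1.10 ± 0.08. Naive and resting state genes rose in 13 of 16 cases and fell in 2, Foxo1 and Id3 (camera adjusted p = 6.3e-05, limma; adjusted p = 0.188 with an estimated correlation), with Ccr7 up by 0.40 ± 0.07 and Il7r by 0.58 ± 0.07, though its other probe set differed by 0.09 (adjusted p = 0.417, limma). Follicular helper genes moved both ways, 6 rising and 4 falling among 11 (camera adjusted p = 0.424, limma); Bcl6 rose by 0.80 ± 0.07 and Pdcd1 fell by 2.00 ± 0.06. Inhibitory receptors fell in 7 of 10 cases and rose in 3 (camera adjusted p = 0.0264, limma; adjusted p = 0.278 with an estimated correlation). NF-kappaB targets fell in 10 of 11 cases (camera adjusted p = 2.12e-05, limma; adjusted p = 0.127 with an estimated correlation). Proliferation genes fell in 16 of 30 cases and rose in 2 (camera adjusted p = 0.000283, limma; adjusted p = 0.322 with an estimated correlation), with Mki67 at -0.94 ± 0.07.

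CD8 T and NK cell markers rose in 6 of 8 cases and fell in 1 (median 1.85, camera adjusted p = 0.00113, limma; adjusted p = 0.148 with an estimated correlation). B cell markers fell in 5 of 9 cases (camera adjusted p = 0.0311, limma; adjusted p = 0.311 with an estimated correlation), Cd79b at -3.01 ± 0.14, and the camera call was lost without ex-iTreg pool 1 (adjusted p = 0.0705). Myeloid markers rose in 5 of 19 cases and fell in 2 (camera adjusted p = 0.527, limma). The poly-A controls differed by -1.36. Adjusted over the list alone, 12 rose and 2 fell among Th1 cell genes, 0 rose and 7 fell among Th2 cell genes, 2 rose and 17 fell among proliferation genes and 5 rose and 3 fell among myeloid markers; the counts of the other lists described for this comparison did not change. In all, 8558 probe sets passed limma's test, 4243 higher and 4315 lower, and the count was 5243 without ex-iTreg pool 1 and 5305 without ex-iTreg pool 2. Without nTreg pool 1 there were 3971 higher and 3305 lower, and without nTreg pool 2 there were 3032 and 4010. The contrast of ex-iTreg with the mean of both reporter-positive populations called 9193 probe sets, 4507 higher and 4686 lower, with 913 at least 2-fold apart (5301 and 5237 calls without ex-iTreg pools 1 and 2).

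**Figure D3:**
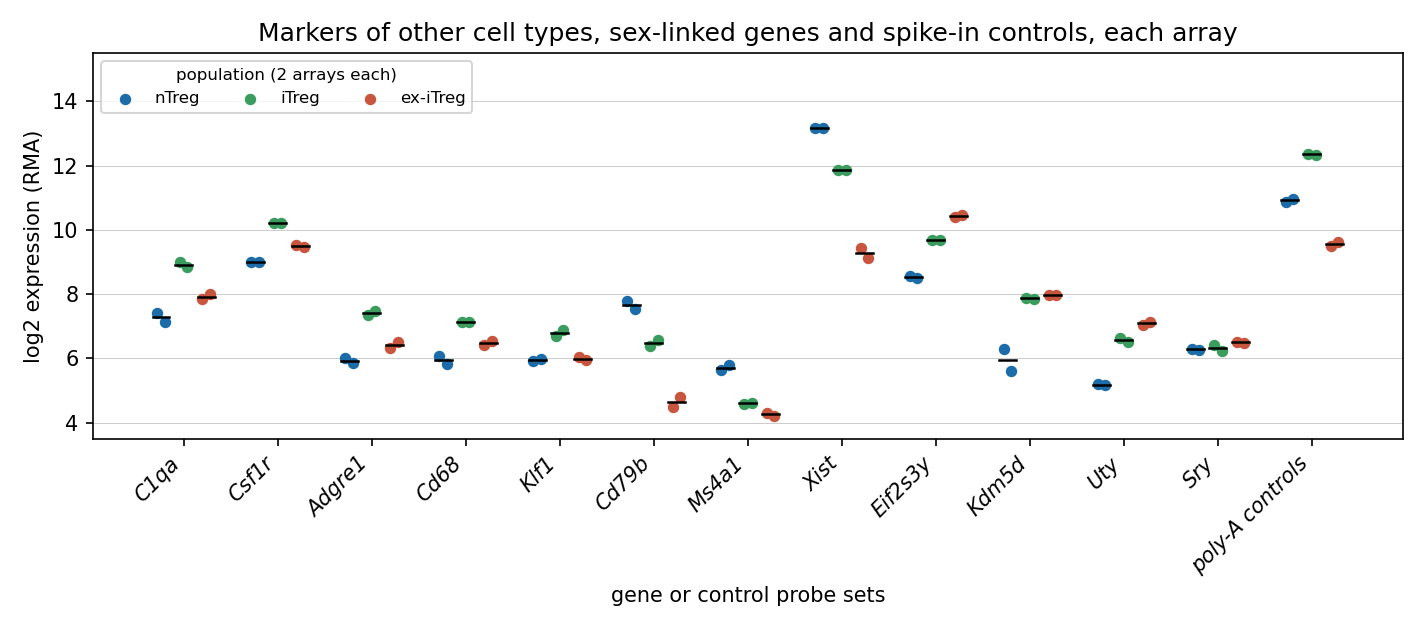
Log2 expression (vertical axis, RMA) of markers of macrophages, erythroid cells and B cells, of Xist and 4 Y-linked genes, and the mean of the poly-A control probe sets (horizontal axis), with 1 point per array, 2 arrays per population, and a bar at each mean. The poly-A controls averaged 10.9 in nTreg, 12.3 in iTreg and 9.55 in ex-iTreg arrays; Xist fell and Eif2s3y rose in the order nTreg, iTreg, ex-iTreg, while Sry stayed between 6.23 and 6.53.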

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

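The poly-A spike-in controls, bacterial transcripts added to RNA before labelling, are outside the gene comparisons and differed between the populations. Their mean was 1.43 log2 units higher in iTreg than nTreg arrays, -2.79 in ex-iTreg minus iTreg and -1.36 in ex-iTreg minus nTreg. The hybridization controls, added later, differed by 0.39, -0.47 and -0.08. The difference of the Gapdh 3' and 5' probe sets was 0.15 in nTreg, 0.45 in iTreg and -0.02 in ex-iTreg arrays. No biological explanation of the spike-in levels was tested.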

How the results depend on the processing

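No array was left out of the main results. Leaving out each array left a lone array that was assumed to vary like the others. Calls for iTreg minus nTreg then ranged from 3420 to 5380, for ex-iTreg minus iTreg from 4971 to 9104, for ex-iTreg minus nTreg from 5243 to 7928, and for ex-iTreg minus the mean of both from 5237 to 8904. Fewer arrays leave fewer residual degrees of freedom. The 2-fold counts ranged from 590 to 661, 859 to 881 and 1270 to 1340, and the lists called from 15 to 16, 14 to 16 and 13 to 15. With camera at the preset correlation, 8 list results gained a call in at least 1 alternative and 2 lost theirs. The stricter filter, which tests fewer probe sets, gave 2-fold counts of 299, 515 and 722. With 1 probe set per gene, 3614, 4316, 4489 and 4657 were called and 247, 390 and 638 were 2-fold apart. Requiring a 2-fold difference beside the adjusted p left 603, 859, 1283 and 913. With an estimated correlation 0, 0 and 0 lists were called. Lists whose estimated correlation lay below the preset 0.01 lost their call too. In iTreg minus nTreg these included thymic markers (correlation -0.045, camera adjusted p 0.000265 with the preset and 0.175 with the estimate) and Th2 cell genes (-0.107, 0.0197 and 0.244). A higher correlation does not account for those losses, and the test with an estimate has only the 3 residual degrees of freedom. The rotation test fry, which does not compare a list with other genes, called 25, 23 and 22. Among lists it called, fry gave the opposite direction to camera for CD8 T and NK cell markers in iTreg minus nTreg (median -0.034, mean 0.01). It also did so for the TGF-beta response in ex-iTreg minus iTreg (median 0.297, mean -0.26). Directions also differed for interferon response and glycolysis in ex-iTreg minus nTreg, which neither test called. Of 140 called results for named genes with another tested probe set, 37 lost their call on at least 1, among them Epcam (-0.141), Il6ra (0.19) and Bcl6 (0.031) in iTreg minus nTreg and Hs3st3b1 (0.059) in ex-iTreg minus nTreg, 5 reversed on at least 1, and 99 kept call and direction on all. Single probe sets reversed Igk in iTreg minus nTreg (-0.704) and, in ex-iTreg minus iTreg, Satb1 (-0.37) and Ighm (0.215). Xaf1 reversed on another probe set (-4.278 in iTreg minus nTreg, -5.161 in ex-iTreg minus nTreg) and in the mean of its probe sets (-1.506 and -2.104); the cause was not tested. Of 381 results for named genes, 37 lost their call without at least 1 array and 0 reversed. Across the 19 settings, 0 shared calls changed sign. Settings that altered only the probe sets kept, the groups in the fit, the spread or the block left each difference of means unchanged. Signs could therefore change only with rescaled values, array weights or a left-out array of the comparison. No rescaling moved the share of higher calls by over 10 points, but in iTreg minus nTreg it was 57.7% without nTreg pool 1 and 41% without nTreg pool 2, against 50.1%. The pool numbers do not pair the arrays, since nothing in the labels ties equal numbers together. Deviations of equally numbered pools correlated at -0.007, -0.088 and -0.04, and a replicate block gave 5853, 8011, 7814 and 8424 calls and ended the calls of 8 results for named genes and of 1 list, glycolysis in iTreg minus nTreg (adjusted p = 0.0555, camera from limma). Signal near background limits Foxp3, which read at most 4.29, and the size of 7, 11 and 16 of the 24 largest differences named per comparison, whose lower mean lay under the filter level. Both means lay under it for 12 of 3202, 32 of 4029 and 11 of 4117 called genes.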

Other observations

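In iTreg relative to nTreg arrays, glycolysis genes rose in 5 of 12 cases (median 0.21, camera adjusted p = 0.047, limma; adjusted p = 0.339 with an estimated correlation), a call lost without nTreg pool 2, iTreg pool 1 or either ex-iTreg array (adjusted p from 0.059 to 0.096) and with a replicate block (adjusted p = 0.0555). Slc2a3, a glucose transporter, rose by 0.54 there, fell by 2.12 in ex-iTreg relative to iTreg arrays and fell by 1.58 relative to nTreg arrays. The glycolysis list did not pass in those comparisons (camera adjusted p = 0.573 and 0.527), where Hk2, a hexokinase, rose by 0.72 and 0.73. Ribosomal protein genes rose in 5 of 19 cases in iTreg and 8 of 19 in ex-iTreg relative to nTreg arrays (camera adjusted p = 0.00495 and 0.000797, limma; adjusted p = 0.274 and 0.278 with an estimated correlation), and 0 of 19 passed the test between ex-iTreg and iTreg (camera adjusted p = 0.236), where an intensity trend called Rpl4, Rpl6 and Rps19 (0.165, 0.112 and 0.081). Cholesterol synthesis genes did not pass (camera adjusted p = 0.0641, 0.658 and 0.518 in the order iTreg minus nTreg, ex-iTreg minus iTreg, ex-iTreg minus nTreg), except in iTreg minus nTreg with the mean of all probe sets (0.0215) or no filter (0.0249), nor did oxidative phosphorylation genes (0.178, 0.658 and 0.374).

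Genes of the TGF-beta response fell in 6 of 10 cases in iTreg relative to nTreg arrays (camera adjusted p = 0.000277, limma; adjusted p = 0.175 with an estimated correlation), Tgif1 at -0.85. In ex-iTreg relative to iTreg arrays 6 rose and 4 fell, with a median of 0.30, a mean of -0.26 and no call (camera adjusted p = 0.511); Tgfbr1 fell by 1.53 and Tgfbr2 rose by 0.94. Relative to nTreg arrays 2 rose and 5 fell (0.195). AP-1 and immediate early genes fell in 7 of 20 cases and rose in 1 in iTreg relative to nTreg arrays (camera adjusted p = 0.00299, limma; adjusted p = 0.191 with an estimated correlation), Nr4a2 at -1.49 (-1.01, -1.48, -1.29 and -0.003 on its other probe sets), and did not pass in the other comparisons (0.083 and 0.424), except in ex-iTreg minus iTreg without iTreg pool 2 (0.043). Interferon response genes rose in 11 of 21 cases in iTreg relative to nTreg arrays (camera adjusted p = 0.000204, limma; adjusted p = 0.274 with an estimated correlation), Oas2 by 1.01, and did not pass between ex-iTreg and nTreg (0.424). Proliferation genes fell in 5 of 30 cases and rose in 2, Cdc20 and Prc1, in iTreg relative to nTreg arrays (camera adjusted p = 0.00534, limma; adjusted p = 0.428 with an estimated correlation), Top2a at -0.62 (0.001 on another probe set), and did not pass between ex-iTreg and iTreg (0.083), where 3 rose and 13 fell, except with no filter (0.00662) or without iTreg pool 2 (0.0312) or ex-iTreg pool 1 (0.0427). Adjusted over the list alone, 7 rose and 0 fell among glycolysis genes, 0 rose and 7 fell among TGF-beta response genes, 2 rose and 8 fell among AP-1 and immediate early genes and 12 rose and 1 fell among interferon response genes in iTreg relative to nTreg arrays. In the order of comparisons above, camera adjusted p-values of lists not called in any comparison were 0.34, 0.083 and 0.0651 for chemokine receptors and homing, 0.867, 0.449 and 0.845 for T cell identity, 0.436, 0.494 and 0.161 for heat shock and stress, 0.436, 0.0849 and 0.127 for dendritic cell markers and 0.393, 0.573 and 0.621 for stromal and endothelial markers. Chemokine receptors and homing did pass with no filter in ex-iTreg minus iTreg (0.0409) and with 4 alternatives in ex-iTreg minus nTreg (from 0.0249 to 0.0429). Dendritic cell markers did so in ex-iTreg minus iTreg without ex-iTreg pool 1 (0.0427) and in ex-iTreg minus nTreg with the mean of all probe sets (0.0357). Remaining values were 0.544 for IL-2 and STAT5 targets and 0.0641 for NF-kappaB targets (0.0385 with no filter) in iTreg minus nTreg, 0.573 and 0.449 for naive genes and inhibitory receptors in ex-iTreg minus iTreg, 0.573 and 0.319 for effector memory genes in ex-iTreg minus iTreg and minus nTreg, 0.969 for CD8 T and NK cell markers in iTreg minus nTreg and 0.622 for erythroid markers in ex-iTreg minus nTreg.

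In all 10 tests of explanations were run, besides 1 scan of gene order. For 4 of them (the neighbours of Thy1, disagreeing probe sets, a second macrophage list and matched random lists) the criterion was written before the result was seen; the rule by which the Thy1 result was judged was changed after it was seen, to need a difference beyond its spread. The matched random lists were drawn when camera had already called the myeloid list, so their outcome was fixed beforehand, and the rule for them was changed afterwards to exclude nothing in that case. The 5 tests of the sex-linked genes and the test of B-lineage genes were chosen only after the result was seen, and rules were changed afterwards for the B-lineage test, to count erythroid markers too, and for the first test of donor sex and of altered Xist, so that Sry alone decides neither.

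Xist was lower and Eif2s3y, Kdm5d and Uty were higher in iTreg and ex-iTreg than in nTreg arrays. Different shares of cells from male and female donors were tested first on all 4 Y-linked genes measured, each of which had to be higher in ex-iTreg than nTreg arrays: 3 were (Eif2s3y by 1.90, Kdm5d by 2.02, Uty by 1.91) and Sry was not (6.28, 6.33 and 6.50; adjusted p = 0.0788, limma), so that criterion was not met, but Sry, a gene of the developing gonad, read only between 6.23 and 6.53 in all arrays and excludes nothing. Altered Xist alone in donors of the same sex would leave Y-linked genes unchanged. Their median in ex-iTreg minus nTreg was 1.902 with Sry and 1.906 without it, so altered Xist alone does not account for them. These differences were known when the test was chosen, so the test adds no evidence of its own. Under the criterion revised after the first result to leave out Sry, 3 of 3 genes were higher. That outcome was already known when the criterion was revised, so it adds no evidence for a difference in donor sex. Male host macrophages as the whole cause were argued against by Eif2s3y and Uty, which rose in ex-iTreg relative to iTreg arrays while myeloid markers fell. However, Kdm5d (0.10) and Sry (0.17) did not pass there and the median of the 4 was 0.349. These values too were known when that test was chosen. A sex difference between the nTreg and iTreg donors alone would leave iTreg and ex-iTreg arrays alike, as both populations carry the Thy1.1 mark of the transferred iTreg cells. It does not account for Xist, Eif2s3y and Uty, which differed by -2.60, 0.75 and 0.53 in ex-iTreg minus iTreg, while Kdm5d and Sry did not pass. The sex of the donors is not given in the labels used here, so mixed donor sex remains a hypothesis.

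Most macrophage transcripts tested were highest in iTreg arrays. A second list of 20 macrophage genes, sharing 0 with the first, had 13 tested members. Of these, 11 were highest in iTreg arrays, with a median of 1.076 in iTreg minus nTreg, but only 9 passed limma's test as higher. Sirpa fell (-0.23) and Cybb was highest in nTreg arrays (9.05). Marco, Cd163, Clec4n and Mertk read under the filter level in nTreg arrays, so the size of their differences is not resolved. Macrophages or their RNA in the iTreg pools may account for the higher macrophage transcripts. The pools were sorted on CD4, EGFP and Thy1.1, but their purity is not given. The most abundant myeloid list members were high in every population. Ctss and S100a9 read 12.5 and 11.9 in iTreg, 12.7 and 11.6 in nTreg, and 12.2 and 11.4 in ex-iTreg arrays. High levels of these members were thus not particular to iTreg arrays. Whether they came from myeloid RNA in every pool or from the T cells was not tested. A lower T cell share stays open, as does expression by the iTreg cells themselves, which was not tested: 4 B-lineage genes had a median of -0.689, but the hosts have no B cells of their own, and erythroid markers (median 0.507) moved with the myeloid ones. Less input RNA also stays open. The myeloid list's median lay at percentile 100 of 10000 lists matched on expression, but that rank follows from camera's call and measures no input. The poly-A controls (12.3) were highest in the same arrays. This match did not extend to ex-iTreg arrays, where the controls were lowest (9.55). There 5 of 19 myeloid markers rose and 2 fell relative to nTreg arrays, and the list was not called.

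A donor chromosome interval carried along with the Thy1.1 allele was a hypothesis for genes that set nTreg arrays apart from both other populations, and the predicted enrichment was not found. Of the 200 tested neighbours of Thy1, 1 was set apart (0.5%, exact 95% interval 0.013 to 2.75%), against 71 of 10795 other genes (0.66%, Fisher's exact test, one-sided p = 0.734). So few genes cannot exclude the interval either. The 1 neighbour was Zc3h12c (-3.19 in iTreg minus nTreg, -3.42 in ex-iTreg minus nTreg), which is among the largest decreases named for iTreg minus nTreg. Whether a donor interval accounts for its difference was not tested. A scan of windows of 50 genes found at most 4 genes set apart in a window, against a median of 3 in 1000 shuffled orders (permutation p = 0.211). A sequence difference between donors was likewise not shown by probe sets that disagree, at 25 of 196 genes (12.8%) in iTreg minus nTreg and 35 of 288 (12.2%) in ex-iTreg minus iTreg (Fisher's exact test, two-sided p = 0.889).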
